A study of Arabidopsis thaliana with 18 samples.

How the data were processed

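Gene expression was measured in whole 7-day-old seedlings of Arabidopsis thaliana, accession Col-0, on 18 Affymetrix arrays. Per the labels, 2 genotypes (wild type, WT, and the spx1 spx2 double mutant) were each sampled in 3 media: complete medium, medium without inorganic phosphate (Pi), and complete medium for 4 h after growth without Pi (resupplied). Each of the 6 groups held 3 arrays that the labels call biological replicates. Total RNA was taken with Trizol and cleaned on columns, and biotin-labelled cRNA was made from 3 micrograms of it.

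The deposited values are on the log2 scale and are RMA summaries, 1 per probe set and array, per the submitters' processing notes. RMA corrects for background, makes the arrays' distributions alike by quantile normalization and summarises the probes of a set by median polish. The log base is not written beside the values. It was inferred from their range, 2.289 to 14.346, and from column medians near 7. The software, its version and the probe set definition are not given in the sources used here. The column medians were 6.84, 6.86 and 6.72 for WT in complete medium, 6.86, 6.89 and 6.81 for WT without Pi, and 6.88, 6.87 and 6.88 for WT resupplied, in replicate order. In the mutant they were 6.87, 6.81 and 6.91 in complete medium, 6.75, 6.79 and 6.82 without Pi, and 6.85, 6.85 and 6.82 after resupply. RMA assumes that most genes keep their level, so a change of total RNA per seedling is not measured.

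The table held 22810 probe sets. The 64 control probe sets were left out of the tests and read separately, which left 22746. Names came from the probe table and were matched to RefSeq by gene identifier. A single gene was named for 13513 probe sets (13436 matched to RefSeq and 77 keeping the table's name), several genes for 503, and 8730 are not named here. The named sets covered 13355 genes. Of these, 147 had several probe sets and 6 of the 147 were called in opposite directions in at least 1 comparison. Where 1 value per gene was needed, the probe set with the highest mean over all arrays was taken.

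All 18 arrays were fitted in 1 model with a mean per group using limma 3.58.1 on R 4.3.3, with moderated errors (12 residual and 6.40 prior degrees of freedom). The 9 comparisons were tested with Benjamini-Hochberg adjustment over all 22746 probe sets at an adjusted p of 0.05. All p values given are two-sided and, unless said otherwise, adjusted. Values are log2 fold changes with their standard error (SE) from the model. The number of arrays, 3 per group, limits the precision. The median standard deviation over probe sets was 0.161 on the log2 scale. The procedure was tested on simulated data with 200 changed probe sets per run. For starvation in WT it recovered 32.5% of changes of 0.5 on the log2 scale, 97.5% of changes of 1 and 100% of changes of 2, with 4, 8 and 10 false calls. For the mutant against WT without Pi it recovered 31.5%, 95.5% and 100%, with 4, 7 and 5 false calls. In the data 11037 probe sets passed for starvation in WT, far more than the 200 changed here, which alters the cutoff that the adjustment sets. The simulated noise was also independent between arrays, while real arrays can share residuals. These shares and false calls therefore test the procedure and do not give the recovery in the real comparisons.

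Named genes follow a rule set before the data were examined. For each comparison it takes the 10 largest rises and the 10 largest falls among probe sets with 1 named gene that passed the test and whose arrays did not overlap between the groups. Ranks given below are among these named genes unless said otherwise, and probe sets without a single named gene can hold larger changes. Non-overlap arises in 10% of unchanged probe sets with 3 arrays against 3. For the 2 interactions only the test applied. Of the 140 largest changes named over the other 7 comparisons, 32 had their lower group under 4.397, the lowest of the arrays' lower quartiles. RMA compresses differences from such dim signals, so these changes are lower bounds. The same holds for 62 of the 1426 changes of list members that passed. Among the 20 genes named for the starvation interaction 5 had such a mean in at least 1 group, and 3 had both means of a genotype there. None of the 20 for the resupply interaction did. From each fixed gene list it also takes up to 4 members with the largest change that passed, or the member with the largest change where none did. Before the data were examined 22 lists with 347 genes were fixed. Only 36 of these genes have a probe set named here, and 9 lists have no measured member. Among the 9 are SPX1 and SPX2 themselves, the Pi transport and signalling genes, the phosphatases and the lipid remodelling genes. The loss of SPX1 and SPX2 transcripts was therefore not checked, and the planned comparison of recovery over the Pi lists was not run. A comparison over all probe sets induced by starvation took its place, chosen after seeing the data. Because so few fixed genes were measured, 22 lists were added from the names in the probe table, before any fold change was computed.

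The 29 lists with at least 3 measured genes were tested with limma's camera, at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. The fold changes of pairs of comparisons were correlated across probe sets, which are not independent replicates. For the pair that shares the WT arrays in complete medium, the chance value came from 100 simulated sets of unchanged groups, and after seeing the data the correlation was also taken with different WT arrays in each comparison. Alternatives fixed before the data were examined were the replicate number as a replicate block, repeated quantile normalization, centring each array on its median, leaving out probe sets dimmer than the median one, eBayes with trend and robust, array weights, only the groups of a comparison, a 2-fold minimum, an adjusted p of 0.01, and leaving out each array in turn. After seeing the data, the 3 arrays with low spike-in signal were also taken as a block or left out. The polyadenylated spike-in controls are bacterial transcripts added to the RNA before labelling. The ratio of 3 prime to 5 prime signal of 3 control genes served as a sign of RNA quality.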

Results

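The data are RMA signals of 22746 probe sets in 18 seedling samples, 3 in each of 6 groups formed by 2 genotypes and 3 Pi supplies. SPX1 and SPX2 encode nuclear SPX-domain proteins known to hold back the Pi starvation regulator PHR1 when Pi is ample. The design asks how seedlings respond to growth without Pi and to 4 h of resupply, and how the double mutant differs from WT in each medium. The arrays separated first by medium: the first principal component carried 48.9% of the variance and the second 27.8%. The 3 prime to 5 prime difference of the ubiquitin control moved with the medium, with means of 1.34 (WT) and 1.3 (mutant) on the log2 scale in complete medium, 1.03 and 1.01 without Pi, and 1.16 and 1.18 after resupply. For GAPDH it ranged from -0.23 to 0.30 over all arrays and for actin from 2.45 to 3.65. The 25S ribosomal RNA control in WT read 11.38 to 12.68 in complete medium, 10.88 to 11.23 without Pi and 9.59 to 10.25 after resupply. In the mutant it read 9.80 to 11.60, 8.53 to 11.18 and 10.08 to 10.40. Whether the signal of organelle-encoded genes follows this control was not tested. Nor was it tested whether their transcripts were labelled alike in all groups. Rises and falls of chloroplast- and mitochondrion-encoded genes given below are therefore changes of array signal, which need not be changes of transcript level. The polyadenylated spike-in controls set 3 arrays apart: WT in complete medium replicate 3, mutant in complete medium replicate 2 and mutant without Pi replicate 1. Their dap control read 7.4 to 7.49, against 9.56 to 10.77 in the other 15 arrays. Lys, phe and thr were also lower in the 3 arrays. A comparison within these 3 alone is not possible, since each comes from a different group. Among the other 15, the WT resupplied arrays read 9.56 to 9.75 for dap and the rest 10.18 to 10.77. The WT resupplied arrays were also the lowest of the 15 for lys, phe and thr. In comparisons that use this group, a labelling difference was not separated from the group itself.

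Growth without Pi raised genes known from the Pi starvation response by up to 220-fold in WT. The largest rises were those of AT5G20790 (7.78 ± 0.16 log2, SE, n = 3 arrays per group) and AT5G17340 (7.63 ± 0.22), genes of unknown function known to respond to low Pi, and of OCT1, an organic cation transporter (7.27 ± 0.15). The calmodulin-like gene AT3G01830 (7.08 ± 0.26) and the AP2/ERF factor gene AT5G52020 (5.84 ± 0.29) were also among the 10 largest, with AT4G27654, AT2G17660, AT4G29780, AT1G08310 and AT3G02840 between 5.92 and 6.60. AT4G39675, a gene known to be induced by low oxygen, had the largest fall (-6.77 ± 0.53). AT1G73600, a phosphoethanolamine methyltransferase gene of phosphocholine synthesis, followed (-4.28 ± 0.21), and then AT5G16030 (-4.25 ± 0.29) and the glutaredoxin gene AT3G62950 (-4.14 ± 0.24). AT1G62510, AT5G14650, AT5G26200, AT4G19430, AT1G33055 and AT5G10040 fell to values between -3.93 and -3.29. Each of these 20 genes had a limma adjusted p of 3.29e-09 or less. The lower group of 9 of them lay under the lower quartile of every array, so their changes are lower bounds: the rises of AT5G17340, AT3G01830, AT4G27654, AT2G17660 and AT3G02840, and the falls of AT4G39675, AT3G62950, AT4G19430 and AT5G10040.

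Gene groups moved with starvation in WT as follows. Of 15 phosphate-related genes picked from those the probe table names, 10 rose and 1 fell (adjusted p = 8.03e-10, and 0.000742 with an estimated correlation). Among them were AT5G09570 (5.40), SAL2 (3.41) and the purple acid phosphatase gene PAP20 (1.57). The list also holds AT5G20790, known to respond to low Pi, so a rise on starvation was likely from the outset. The MYB factor genes AT3G25790 (HHO1, 2.36), AT1G68670 (HHO2, 1.71) and AT1G25550 (HHO3, 1.46), from the nitrate list, rose as 3 of 3, over all probe sets and adjusted over the list alone (adjusted p = 0.000256, and adjusted p = 0.0525 with an estimated correlation). Calmodulin-like and U-box stress genes rose in 12 of 13 cases and fell in 1, with CML37 at 5.67 or more, STZ (the zinc finger gene ZAT10) at 5.33 and PUB23 at 3.87 (adjusted p = 4.07e-11, and 0.00788 estimated). STZ, CML38 (2.98) and WRKY53 (2.55) form the measured touch list, 3 of 3 up both over all probe sets and adjusted over the list alone (adjusted p = 2.4e-05, and 0.00788 estimated). Cold and drought protection genes rose in 8 of 11 cases and fell in 1, with COR15B at 4.26, COR15A at 4.07 and the dehydrin gene LTI30 at 3.16 (adjusted p = 1.37e-05, and 0.00788 estimated). Anthocyanin genes rose in 4 of 5 cases, the same count adjusted over the list alone, led by the glucosyltransferase gene AT4G14090 (2.09 ± 0.19) and the xylosyltransferase gene UF3GT (1.60 ± 0.18). Their call was lost with an estimated correlation (adjusted p = 0.00171 preset, adjusted p = 0.215 with an estimated correlation). Cytosolic ribosomal protein genes fell in 85 of 111 cases and rose in 1, by a median of -0.43. Their adjusted p was 6.39e-09, and adjusted p = 0.337 with an estimated correlation. Nuclear photosynthesis genes picked by name fell in 16 of 22 cases, with the assembly factor genes LPA19 (-1.87) and PAM68 (-1.86) lowest (adjusted p = 4.6e-05, and adjusted p = 0.287 with an estimated correlation). Chloroplast-encoded genes of transcription and translation fell in 14 of 22 cases, among them rps14 (-3.0), and those of the photosystems in 15 of 37, among them petN (-2.91). Their adjusted p of 0.00503 and 0.024 became adjusted p = 0.644 and 0.683 with an estimated correlation, and 0.059 and 0.0858 without the dimmer probe sets. Among single list members, the starch synthesis gene APL3 rose by 2.41 ± 0.25, the clock gene GI by 1.31 ± 0.12 and the root hair expansin genes EXPA7 and EXPA18 by 1.01 ± 0.20 and 0.96 ± 0.22. The 1 measured gene of the fixed list for root tissue other than hairs rose by 0.79. Samples were whole seedlings, so a changed share of roots was not separated from changes within organs. The iron-deficiency factor gene BHLH101 fell (-2.28 ± 0.28), and so did the defensin gene PDF1.2 (-0.96 ± 0.12). The changes of CML37, PAP20 and BHLH101 are lower bounds, with the lower group under the lower quartile of every array.

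Starvation in WT changed 11037 of 22746 probe sets, 4649 up and 6388 down (42.1% up, and 38.0% with each array centred), of which 3435 changed at least 2-fold (2015 up, 1420 down). The median of all probe sets was -0.11, and relative to it the ribosomal protein median was lower and the direction of each list call above was kept when each array was centred. With the low spike-in arrays as a block 11584 probe sets passed, and 11255 within the other 15 arrays. The largest rise without a gene named here, that of a single probe set, was 8.72 ± 0.23.

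**Figure D1:**
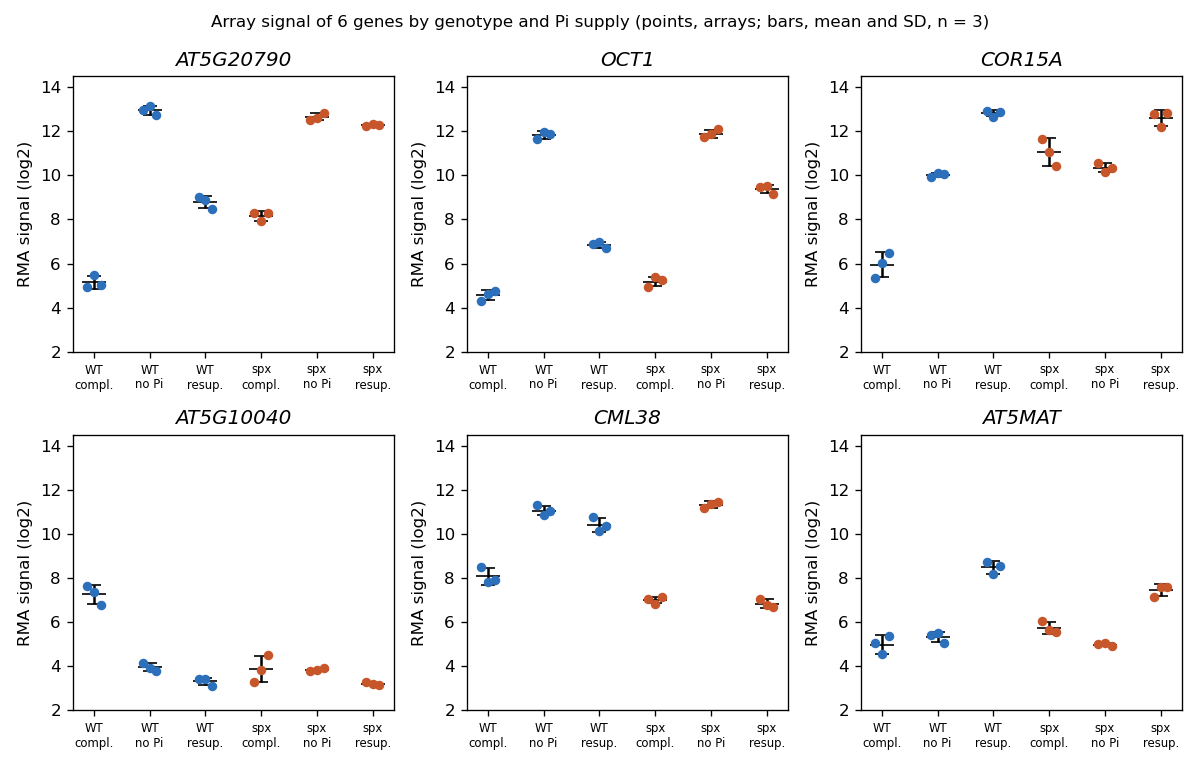
RMA signal (log2, vertical axis) of 6 genes in the 6 groups (horizontal axis); points are arrays, bars the mean and SD of 3 arrays. AT5G20790 averaged 5.16 in WT in complete medium and 8.16 in the mutant, 12.94 and 12.65 without Pi, and 8.79 and 12.28 after resupply.

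The double mutant without Pi was compared with the mutant in complete medium to see its own starvation response. The genes with the largest rises included those seen in WT: AT5G17340 (7.48 ± 0.22), AT4G27654 (7.23 ± 0.19), OCT1 (6.71 ± 0.15), AT2G17660 (6.44 ± 0.19) and AT5G52020 (5.88 ± 0.29). CML37 (5.44 ± 0.18), AT5G38700 (5.26 ± 0.18) and the AP2/ERF factor gene AT1G19210 (5.23 ± 0.13) followed. AT1G73600 had the largest fall (-5.31 ± 0.21). The bHLH factor gene AT1G10585 (-4.87 ± 0.30), AT4G39675 (-4.31 ± 0.53), AT5G37990 (-4.02 ± 0.21) and the glutaredoxin genes AT3G62950 (-3.80 ± 0.24) and AT4G15700 (-2.97 ± 0.15) also fell, each of these genes with an adjusted p of 1.96e-06 or less. Lower bounds by the same rule are the rises of AT5G17340, AT4G27654, AT2G17660 and CML37 and the falls of AT1G10585, AT4G39675, AT3G62950 and AT4G15700.

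Phosphate-related genes rose in 10 of 15 cases in the mutant and fell in 3 (adjusted p = 1.16e-05, and 0.0109 with an estimated correlation). Calmodulin-like and U-box genes rose in 11 of 13 cases and fell in 2 (adjusted p = 2.39e-09, and 0.0159 estimated). Touch genes rose in 3 of 3 cases, also adjusted over the list alone, with CML38 at 4.32 ± 0.18 (adjusted p = 0.000141, and 0.0159 estimated). Ribosomal protein genes fell in 98 of 111 cases and rose in 1, by a median of -0.58 (adjusted p = 4.11e-18, and adjusted p = 0.244 with an estimated correlation). Nucleolar genes fell in 4 of 4 cases, also adjusted over the list alone, with the ribosome biogenesis gene AT3G05060 at -1.52 ± 0.24 (adjusted p = 0.0159, and adjusted p = 0.29 with an estimated correlation, and 0.0993 without the dimmer probe sets). PDF1.2 fell by 2.63 ± 0.12 on the log2 scale. Of the anthocyanin genes 1 rose and 2 fell, and adjusted over the list alone 1 rose and 3 fell. In all 10019 probe sets changed, 4026 up and 5993 down (40.2% up, and 48.8% with each array centred), with 11143 under the spike-in block and 9863 within the other 15 arrays. Across probe sets the starvation changes of the mutant and of WT, which share no array, had a correlation of 0.828. Both rose at 3069 probe sets, against 823 for independent calls, and both fell at 4214, against 1683. These counts were added after seeing the data.

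In complete medium the largest rises in the mutant over WT included cold- and jasmonate-related genes. COR15A, a cold-regulated chloroplast protein gene, was higher by 5.10 ± 0.27 log2 (SE, n = 3 arrays per group), COR15B by 3.89 ± 0.22 and the cold and clock regulator gene COR27 by 3.67 ± 0.18. The jasmonate-related oxygenase genes AT2G38240 (4.49 ± 0.29) and JRG21 (3.92 ± 0.31), the bHLH factor gene AT1G10585 (4.51 ± 0.30), AT2G23910 (4.82 ± 0.18), AT1G07050 (3.81 ± 0.18), the glutathione transferase gene GSTU25 (3.70 ± 0.22) and AT5G62360 (3.58 ± 0.24) completed the 10 largest rises. The largest falls were of genes known to be induced by low oxygen: AT5G10040 (-3.37 ± 0.22), AT2G17850 (-3.09 ± 0.33), AT4G33560 (-2.67 ± 0.28), AT3G29970 (-2.45 ± 0.22), AT4G39675 (-2.23 ± 0.53), AT1G19530 (-2.18 ± 0.41), AT4G27450, AT3G27220 and AT1G33055. AT5G26200 (-1.76 ± 0.20) was also among the 10. Each had an adjusted p of 0.00595 or less. The changes of AT2G23910, AT1G10585, AT1G07050, COR27, AT5G10040 and AT3G29970 are lower bounds, with the lower group under the lower quartile of every array.

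Phosphate-related genes were higher in 6 of 15 cases and lower in none that passed (adjusted p = 3.67e-07, and 0.00335 with an estimated correlation). AT2G04460 (3.12) and AT5G20790 (3.01), induced by starvation in WT, led them. Cold and drought genes were higher in 6 of 11 cases and lower in 2, with LTI30 at 3.43 (adjusted p = 2.47e-05, and 0.0174 estimated). Jasmonate genes picked by name were higher in 5 of 10 cases, with PDF1.2 at 1.55 ± 0.12 and PDF1.2b at 1.52, and lower in 1, the thionin gene THI2.2 (adjusted p = 0.00112, and 0.0244 estimated). UDP glycosyltransferase genes were higher in 17 of 47 cases, led by the hydroxycinnamate glucosyltransferase gene UGT84A1 (2.64). Their adjusted p was 9.84e-09, and adjusted p = 0.054 with an estimated correlation. Anthocyanin genes were higher in 4 of 5 cases, also adjusted over the list alone, among them UGT78D2 (1.49 ± 0.18) and AT4G14090 (1.37 ± 0.19), with an adjusted p of 0.000163, and adjusted p = 0.143 with an estimated correlation. Calmodulin-like and U-box genes were higher in 7 of 13 cases and lower in 2 (adjusted p = 0.000181, adjusted p = 0.125 with an estimated correlation, and adjusted p = 0.0781 without the dimmer probe sets). WRKY53 was higher by 2.0 ± 0.16 and STZ by 1.23 ± 0.15, while CML38 was lower (-1.07 ± 0.18). GI was higher by 0.98 ± 0.12, APL3 by 1.3 ± 0.24 and the 1 measured gene of the root tissue list by 0.44. AT3G13610, the coumarin synthesis gene F6'H1, was lower (-1.01 ± 0.12). Nuclear photosynthesis genes picked by name were lower in 8 of 22 cases (adjusted p = 0.000404, and adjusted p = 0.407 with an estimated correlation).

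In complete medium 4146 probe sets differed between the genotypes, 2293 higher and 1853 lower in the mutant, and 733 by at least 2-fold (623 higher, 110 lower). The share that was higher, 55.3%, became 41.7% when each array was centred. Leaving out mutant replicate 1 gave 2370 probe sets, a fit to these 2 groups alone 1525, the low spike-in arrays as a block 5547 and the other 15 arrays 3523.

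Without Pi the genotypes differed little. The chloroplast-encoded photosystem II genes psbI (2.17 ± 0.35 log2, SE, n = 3 arrays per group) and psbK (2.09 ± 0.37) were higher in the mutant, as were AT2G37870 (1.5 ± 0.19), AT4G32340 (1.42 ± 0.14), AT4G01390 (1.19 ± 0.13) and AT1G62510 (1.05 ± 0.22). Lower were AT3G28220 (-1.65 ± 0.29), AT1G66100 (-1.15 ± 0.22), AT3G05640 (-1.13 ± 0.14), AT3G21620 (-1.13 ± 0.18), AT1G26380 (-1.08 ± 0.23) and AT1G05700 (-1.03 ± 0.13). Scpl30, AT1G76960, AT5G52750 and AT3G46110 were the other rises, between 0.80 and 0.97, and AT3G24510 (-0.94) and AT4G12500 (-0.93) the other falls named. Each had an adjusted p of 0.0447 or less, and the fall of AT3G24510 is a lower bound. Anthocyanin genes were lower in 3 of 5 cases, also adjusted over the list alone: AT4G14090 (-1.01 ± 0.19), the dihydroflavonol reductase gene DFR (-0.93 ± 0.18) and UF3GT (-0.82 ± 0.18). Their adjusted p was 5.08e-06, and adjusted p = 0.149 with an estimated correlation. Over 37 chloroplast-encoded photosystem and electron transport genes, psbI and psbK were the 2 that passed and the median was -0.03. The 15 phosphate-related genes had changes between -0.41 and 0.13, and AT5G20790 was at -0.29 and OCT1 at 0.06. GI differed by -0.01 ± 0.12 (adjusted p = 0.979).

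In all 189 probe sets differed without Pi, 77 higher and 112 lower, and 28 by at least 2-fold. The largest difference, that of a probe set without a single named gene, was -3.12 ± 0.24 (limma adjusted p = 1.09e-06). The share higher was 40.7%, and 62.8% with each array centred. The count was 125 with a replicate block, 667 with array weights, 240 with the spike-in block and 157 within the other 15 arrays. Leaving out WT replicate 1 or 2 gave 110 or 49, and mutant replicate 1 or 2 gave 105 or 66. With 1 array left out a group has 2.

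The test of the genotype difference in the starvation response named genes with a different change in the 2 genotypes. It equals the genotype difference without Pi less that in complete medium. Since only 189 probe sets differed without Pi, the genes and lists given here largely repeat the complete-medium comparison, with the sign reversed and from the same arrays. They are not separate evidence. AT2G23910 (-5.15 ± 0.25 log2, SE, n = 3 arrays per group), COR15A (-4.77 ± 0.38), JRG21 (-4.62 ± 0.44), AT1G10585 (-4.60 ± 0.43), AT3G28220 (-4.33 ± 0.41) and AT2G38240 (-3.98 ± 0.41) changed less, or fell, in the mutant. COR15A rose by 4.07 ± 0.27 in WT, and its change in the mutant was -0.70. TBL26, COR15B, GSTU25 and AT4G30650 lay between -3.92 and -3.46. In the other direction were AT2G17850 (3.39 ± 0.47), AT5G10040 (3.25 ± 0.32), psbI (2.71 ± 0.49), psbK (2.66 ± 0.53), AT4G01390 (2.61 ± 0.18), AT3G29970 (2.47 ± 0.31), AT4G33560 (2.4 ± 0.40) and AT1G33055 (2.38 ± 0.25). PsbI fell in WT (-2.63) and was at 0.07 in the mutant. Both mutant means of AT5G10040 and AT3G29970, and both WT means of AT1G10585, lay under the lower quartile of every array. A fall of these genes as large as that in the other genotype could not be seen there, so their values do not show that the response depends on genotype. AT4G39675 and AT2G23910 also had at least 1 mean that low, and their values are not exact. The calls of atpA (2.49 ± 0.73) and AT4G39675 (2.46 ± 0.75) ended under eBayes with trend and robust.

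Among the lists, 6 interactions with starvation passed with either correlation. Phosphate-related genes had 6 of 15 members with a smaller change in the mutant (adjusted p = 1.57e-07, and 0.00297 with an estimated correlation), among them AT5G20790 (-3.30) and AT2G04460 (-2.98). Cold and drought genes had 6 of 11 lower and 1 higher (adjusted p = 3.35e-05, and 0.019 estimated). Jasmonate genes picked by name had 5 of 10 lower and 1 higher (adjusted p = 0.00066, and 0.019 estimated), among them PDF1.2 (-1.67 ± 0.17). Anthocyanin genes had 4 of 5 lower, and 5 adjusted over the list alone (adjusted p = 1.57e-07, and 0.0354 estimated), with AT4G14090 at -2.38 ± 0.26. UDP glycosyltransferases had 20 of 47 lower (adjusted p = 2.57e-10, and 0.0323 estimated), and the citrate cycle list 3 of 14 (adjusted p = 0.00359, and 0.0414 estimated). The 1 measured gene of the root tissue list also passed, at -0.78. In all 2762 probe sets passed, 1002 higher and 1760 lower. The share higher, 36.3%, became 61.9% with each array centred. Without mutant replicate 1 in complete medium the count was 1687, in a fit to the 4 groups alone 1580, with the spike-in block 3279 and within the other 15 arrays 2107.

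Resupply for 4 h lowered single starvation-induced genes in WT and raised ribosome assembly genes. Cytosolic ribosomal protein and anthocyanin genes also rose one by one, but both lists lost their call with an estimated correlation (adjusted p = 0.0618 each). AT5G17340 fell by 5.63 ± 0.22 on the log2 scale (SE, n = 3 arrays per group), OCT1 by 4.98 ± 0.15, AT2G04460 by 4.75 ± 0.14, AT1G08310 by 4.50 ± 0.15 and AT5G20790 by 4.15 ± 0.16. Scpl22, FHL, the U-box gene AT4G25160, AT3G43110 and AT2G23270 lay between -4.42 and -3.84. AT1G10585 (5.05 ± 0.30), AT5G37990 (4.72 ± 0.21), AT3G26460 (3.61 ± 0.25), AT5G47330 (3.58 ± 0.36) and AT2G48080 (3.48 ± 0.20) had the largest rises. UGT84A1 (3.37 ± 0.21), AT2G22590, AT1G07050, AT2G23910 and the anthocyanin malonyltransferase gene AT5MAT (3.15 ± 0.20) followed. Each had an adjusted p of 4.64e-07 or less, and the changes of AT1G10585, AT3G26460, AT1G07050 and scpl22 are lower bounds.

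Cytosolic ribosomal protein genes rose in 103 of 111 cases on resupply in WT, by a median of 0.76, led by AT2G32220 (2.47) and AT5G39850 (2.19). Their adjusted p was 9.25e-41, and adjusted p = 0.0618 with an estimated correlation. Ribosome assembly and RNA polymerase I genes rose in 11 of 11 cases, with the polymerase subunit gene NRPA1 at 2.06 and YAO at 1.87 (adjusted p = 6.28e-11, and 0.0366 estimated). Nucleolar genes from the fixed list, AT3G15460 (1.85 ± 0.14), AT3G05060 (1.63 ± 0.24), AT2G40360 (1.33 ± 0.12) and AT5G14520 (1.11 ± 0.13), rose in 4 of 4 cases, also adjusted over the list alone (adjusted p = 9.6e-05, and adjusted p = 0.074 with an estimated correlation). Anthocyanin genes rose in 5 of 5 cases, also adjusted over the list alone, with UF3GT at 2.95 ± 0.18 (adjusted p = 6.69e-07, and adjusted p = 0.0618 with an estimated correlation). Phosphate-related genes fell in 8 of 15 cases and rose in 3, the latter including the multicopper oxidase genes LPR1 (1.5) and LPR2 (0.58) (adjusted p = 0.000754, and 0.0366 estimated). The nitrate list fell in 3 of 3 cases, also adjusted over the list alone, with AT1G68670 at -1.54 ± 0.10 (adjusted p = 0.00192, and adjusted p = 0.0777 with an estimated correlation). Nuclear photosynthesis genes from the fixed list fell in 6 of 6 cases, also adjusted over the list alone, with LHCB4.2 at -1.14 ± 0.10 (adjusted p = 0.000717, and adjusted p = 0.21 with an estimated correlation). Of the touch genes, STZ was at -0.09 ± 0.15 and WRKY53 at 0.02 (adjusted p = 0.689 and 0.942), and CML38 fell (-0.64 ± 0.18). GI was at 0.14 ± 0.12 (adjusted p = 0.422). In all 8517 probe sets changed, 4191 up and 4326 down (49.2% up, and 46.4% with each array centred), 1917 of them at least 2-fold. The count was 9658 with the spike-in block and 9715 within the other 15 arrays. None of the 3 low spike-in arrays belongs to these 2 groups, but the resupplied WT arrays had the lowest spike-in signal of the other 15. A labelling difference was therefore not separated from resupply in WT.

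**Figure D2:**
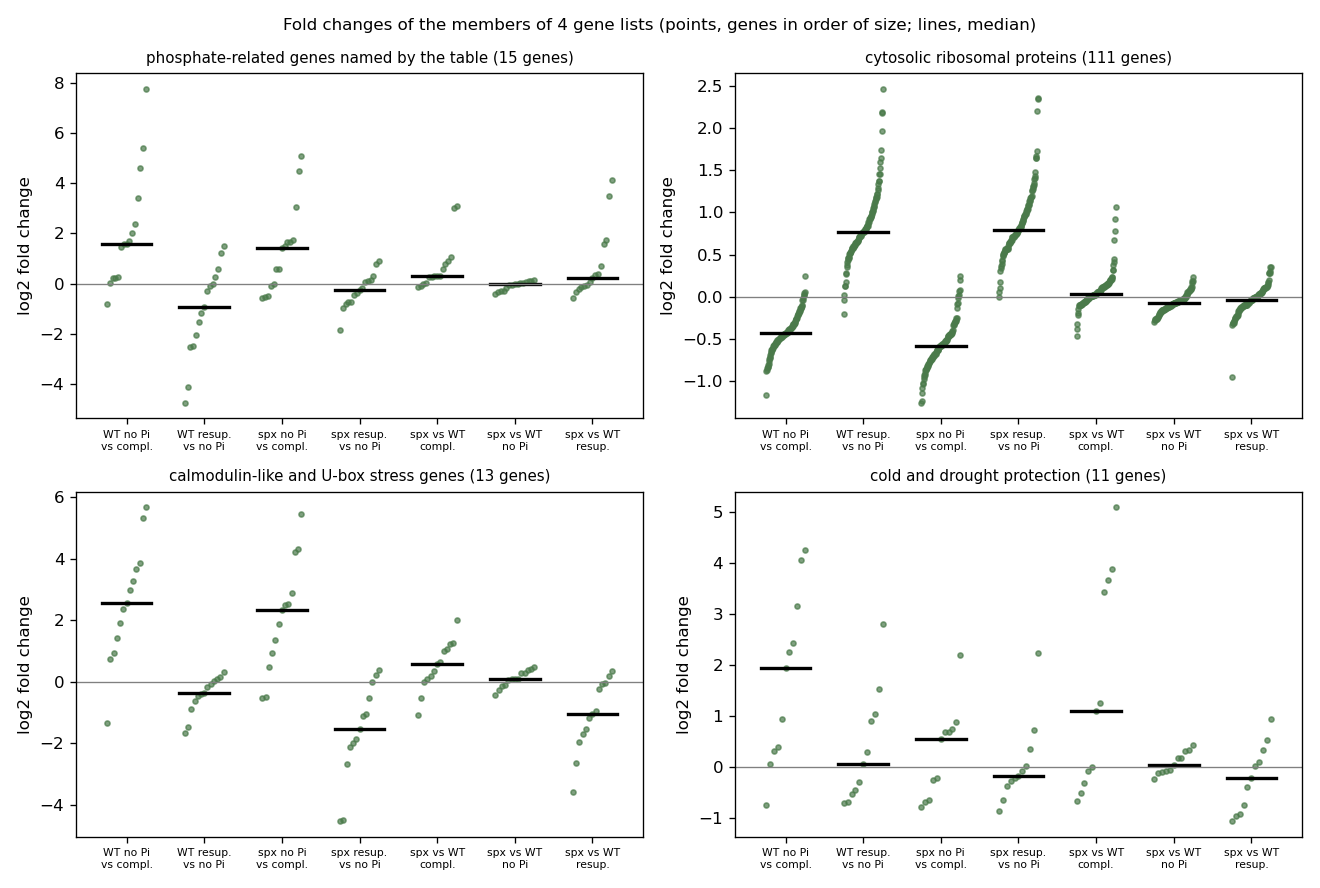
Log2 fold changes (vertical axis) of the members of 4 gene lists in 7 comparisons (horizontal axis); points are genes in order of size and lines are medians. The median of 111 cytosolic ribosomal protein genes was -0.43 on starvation and 0.76 on resupply in WT, and -0.58 and 0.79 in the mutant.

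In the mutant, resupply raised AT1G10585 (5.51 ± 0.30 log2, SE, n = 3 arrays per group), AT5G37990 (4.89 ± 0.21), JRG21 (4.54 ± 0.31), AT3G26460 (3.86 ± 0.25), AT1G14120 (3.46 ± 0.16) and UGT84A1 (3.33 ± 0.21). Among named genes the largest falls were those of AT2G17660 (-5.73 ± 0.19), AT5G38700 (-4.88 ± 0.18), AT1G19210 (-4.82 ± 0.13), AT3G02840 (-4.67 ± 0.18), CML37 (-4.54 ± 0.18), CML38 (-4.49 ± 0.18) and AT4G29780 (-4.47 ± 0.15). The largest falls of probe sets without a single named gene were -7.81 ± 0.25 and -7.36 ± 0.20. The expansin-like gene EXLA3 (-4.46 ± 0.15), the calmodulin-like gene AT1G76640 (-4.45 ± 0.25) and the AP2/ERF gene AT1G22810 (-4.19 ± 0.22) also fell. AT5G20790 was at -0.37, against -4.15 in WT. Each of the genes called here as risen or fallen had an adjusted p of 1.2e-09 or less, and the rises of AT1G10585 and AT3G26460 are lower bounds.

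Ribosomal protein genes rose in 106 of 111 cases in the resupplied mutant, by a median of 0.79 (adjusted p = 2.61e-35, and adjusted p = 0.0934 with an estimated correlation). Anthocyanin genes rose in 5 of 5 cases, also adjusted over the list alone, with UF3GT at 2.78 ± 0.18 (adjusted p = 2.78e-05, and adjusted p = 0.106 with an estimated correlation). Touch genes fell in 3 of 3 cases, also adjusted over the list alone (adjusted p = 0.000104, and 0.0496 estimated), and calmodulin-like and U-box genes fell in 10 of 13 cases and rose in 1 (adjusted p = 4.26e-07, and adjusted p = 0.0618 with an estimated correlation). Chloroplast-encoded photosystem genes fell in 20 of 37 cases and chloroplast-encoded genes of transcription and translation in 14 of 22, with atpA at -2.36 and rpl22 at -2.35. Their adjusted p of 0.000476 and 4.13e-05 became adjusted p = 0.63 and 0.498 with an estimated correlation. The root hair genes EXPA18 (1.98 ± 0.22) and EXPA7 (1.91 ± 0.20) rose. In all 9741 probe sets changed, 5350 up and 4391 down (54.9% up, and 49.0% with each array centred), with 10560 under the spike-in block and 10172 within the other 15 arrays. Across probe sets the resupply changes of the 2 genotypes, which share no array, had a correlation of 0.754, with 3274 probe sets up in both (986 for independent calls) and 2651 down in both (835). These counts were also added after seeing the data.

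After resupply some genes of the starvation response were higher in the mutant than in WT, and the touch genes were lower. Over all 1641 probe sets induced by starvation in both genotypes on average, 330 were higher and 441 lower, and the call of the phosphate-related list was lost with an estimated correlation (adjusted p = 0.00287 preset, adjusted p = 0.0535 with an estimated correlation). AT2G04460 was higher by 4.14 ± 0.14 log2 (SE, n = 3 arrays per group), AT5G20790 by 3.49 ± 0.16, AT5G17340 by 3.36 ± 0.22 and OCT1 by 2.52 ± 0.15. AT3G43110 (2.44 ± 0.20), AT1G08310 (2.36 ± 0.15), AT4G23000 (2.3 ± 0.14), AT3G44510 (2.19 ± 0.11), AT4G35750 (1.99 ± 0.10) and AT1G23140 (1.97 ± 0.18) followed. The AP2/ERF factor genes AT1G19210 (-3.90 ± 0.13) and ORA47 (-3.08 ± 0.14), the calmodulin-like genes CML38 (-3.58 ± 0.18) and CML37 (-2.65 ± 0.18) and EXLA3 (-3.15 ± 0.15) were lower. AT3G02840, AT4G29780, AT5G38700, AT4G27654 and the nucleolar gene AT1G06720 lay between -3.22 and -2.58. Each had an adjusted p of 3.71e-06 or less.

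Touch genes were lower in 3 of 3 cases in the resupplied mutant, also adjusted over the list alone (adjusted p = 4.04e-07, and 0.0059 with an estimated correlation), with STZ at -1.95 ± 0.15. Calmodulin-like and U-box genes were lower in 8 of 13 cases (adjusted p = 8.31e-09, and 0.0257 estimated). Phosphate-related genes were higher in 6 of 15 cases and lower in 1. Anthocyanin genes were lower in 4 of 5 cases, and in 5 adjusted over the list alone, with DFR at -1.24 ± 0.18 (adjusted p = 3.24e-05, and adjusted p = 0.107 with an estimated correlation). Nucleolar genes were lower in 4 of 4 cases, also adjusted over the list alone, with AT3G05060 at -1.49 ± 0.24 (adjusted p = 0.000636, and adjusted p = 0.107 with an estimated correlation). Mitochondrion-encoded genes were higher in 9 of 16 cases, led by cox2 (1.13). Their adjusted p was 1.35e-05, adjusted p = 0.0971 with an estimated correlation, and adjusted p = 0.442 without the dimmer probe sets. Chloroplast-encoded genes of transcription and translation were lower in 9 of 22 cases, led by rpl22 (-2.51), with an adjusted p of 1.26e-06, and adjusted p = 0.504 with an estimated correlation. EXPA7 and EXPA18 were higher by 1.25 ± 0.20 and 1.13 ± 0.22, and GI was at 0.04 ± 0.12 (adjusted p = 0.874).

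After resupply 5249 probe sets differed between the genotypes, 2596 higher and 2653 lower in the mutant, and 748 by at least 2-fold (193 higher, 555 lower). The share higher was 49.5%, and 55.7% with each array centred. Leaving out WT replicate 1 or 3, or mutant replicate 2 or 3, gave 3432, 3437, 3403 and 3311. Array weights gave 9266, a fit to these 2 groups 8094, the spike-in block 6616 and the other 15 arrays 6671.

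The test of the genotype difference in the resupply response named mostly the same genes as the comparison after resupply. AT2G04460 (4.00 ± 0.19 log2, SE, n = 3 arrays per group), AT5G20790 (3.78 ± 0.23), AT5G17340 (3.33 ± 0.32), AT3G43110 (2.72 ± 0.28), AT1G08310 (2.49 ± 0.22) and OCT1 (2.46 ± 0.21) had the largest positive differences, being less reduced in the mutant. CML38 (-3.84 ± 0.25), AT1G19210 (-3.80 ± 0.19), EXLA3 (-3.58 ± 0.21), AT3G02840 (-3.51 ± 0.26), AT4G29780 (-3.34 ± 0.21), AT5G38700 (-3.24 ± 0.26), CML37 (-3.05 ± 0.25) and ORA47 (-2.93 ± 0.20) had the largest negative ones. Each had an adjusted p of 3.6e-06 or less. Touch genes passed in 3 of 3 cases, all lower, also adjusted over the list alone (adjusted p = 1.27e-08, and 0.00246 with an estimated correlation). Calmodulin-like and U-box genes passed in 8 of 13 cases, all lower (adjusted p = 4.56e-10, and 0.0104 estimated), and phosphate-related genes in 6 of 15, all higher (adjusted p = 8.48e-05, and 0.0104 estimated). EXPA7 (1.45 ± 0.29) and EXPA18 (1.26 ± 0.31) rose more in the mutant. The anthocyanin list was past neither setting (adjusted p = 0.22). In all 2638 probe sets passed, 1400 higher and 1238 lower, and of those with at least a 2-fold difference 353 were higher and 515 lower. The share higher, 53.1%, became 45.4% with each array centred. Leaving out WT resupplied replicate 1 or 3, or mutant resupplied replicate 2 or 3, gave 1692, 1709, 1715 and 1751. Array weights gave 5843, a fit to the 4 groups 4017, the spike-in block 3941 and the other 15 arrays 3570.

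Over the 1641 probe sets whose starvation rise averaged at least 2-fold over both genotypes, the median rise was 1.86 in WT and 1.51 in the mutant. This set was defined after seeing the data and uses the arrays without Pi that the falls also use. On resupply its median was -0.68 in WT and -0.83 in the mutant, with 1077 and 1096 probe sets down, 912 of them in both. The genotype difference on resupply had a median of -0.08, with 281 probe sets higher and 404 lower. In complete medium 603 of the 1641 were higher in the mutant and 67 lower. After resupply 330 were higher and 441 lower.

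The WT starvation changes and the mutant's changes in complete medium were compared across probe sets. They share the WT arrays in complete medium, which alone give a correlation near 0.5 between unchanged groups, and theirs was 0.515. Their covariance, 0.192, was far above the simulated 0.0107, a difference of 0.181. In both, 1507 probe sets rose (469 for independent calls, and 0 on average in the simulation) and 1272 fell (520, and 0.02). Another 148 rose then fell (379) and 169 fell then rose (644). Neither chance value holds both the real effects and the shared arrays, so part of the excess may come from the shared arrays. With 1 of the 3 WT arrays in one comparison and the others in the other, a test added after seeing the data, the correlation was 0.348 to 0.450 over the 6 ways of doing so and the covariance 0.156 to 0.178. These splits remove the noise of single arrays, but not a state shared by the WT seedlings in complete medium. Of the pairs across genotypes and media without a shared array, WT resupply and the mutant in complete medium had a correlation of 0.285, with 959 probe sets up in both (422 for independent calls), 752 down in both (352), 147 up then down (341) and 410 down then up (436). WT starvation and the mutant after resupply had a correlation of -0.0503, with 823 up in both (531), 981 down in both (745), 787 up then down (542) and 765 down then up (729).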

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

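The tests of explanations in this part were chosen only after the results were seen. The reassignments of genotype labels were planned before.

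The 2 tests of whether a response depended on genotype gave 2762 probe sets for starvation and 2638 for resupply. For starvation the largest differences among probe sets with 1 named gene were AT2G17850 (3.389), AT5G10040 (3.249) and psbI (2.708) on the positive side. On the negative side they were AT2G23910 (-5.148), COR15A (-4.768) and JRG21 (-4.618). AT5G10040 lay under the lower quartile of every array in both mutant groups, so a fall as large as that in WT could not be seen there. For resupply the largest among such probe sets were AT2G04460 (4.005), AT5G20790 (3.781) and AT5G17340 (3.325), and CML38 (-3.844), AT1G19210 (-3.797) and EXLA3 (-3.575). Probe sets without a single named gene held larger differences, up to -5.888 for starvation and -5.889 for resupply. When genotype labels were reassigned within each medium, 1 of 100 assignments, the real one, gave as many calls for starvation, with 2404 as the highest other, from an assignment that kept the genotypes apart in complete medium. For resupply 3 of 100 gave as many, with 3460 as the highest other, and both others kept the genotypes apart in the resupplied arrays. Both shares are under 0.05, which argues against an accidental assignment of genotype to the arrays. Reassignment also removes a genotype difference within a single medium, so these shares do not test whether the response itself depended on genotype. Among assignments that did not keep the genotypes apart in complete medium (starvation) or in the resupplied arrays (resupply), the highest gave 422 and 9.

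AT2G23910, COR15A and JRG21 belong to a shift of the mutant in complete medium in the direction of the WT resupply response. With separate WT arrays its correlation with WT starvation was 0.348 to 0.450, and COR15A rose by 4.07 on starvation. Both comparisons still subtract WT seedlings in complete medium, so a state shared by those seedlings could give this. Whether the shift is particular to resupply could therefore not be told. The low spike-in arrays alone did not give the shift, since the correlation was 0.275 without them and 0.285 with all. A labelling batch was not excluded: none of these arrays is in the WT resupply comparison. The lower spike-in signal of the WT resupplied arrays coincides with their group and was not tested. The shift was seen in each of the 3 mutant arrays in complete medium taken alone, at 0.337, 0.258 and 0.168 in replicate order. Each was set against the same WT mean, which can by itself make all 3 positive. It was therefore not excluded that a single mutant array led the shift. Leaving out replicate 1 lowered the probe sets that differed in complete medium from 4146 to 2370. A later time of day at harvest stays open: GI, the 1 measured gene of the fixed clock lists, changed by 0.14 on WT resupply (adjusted p = 0.422) but by 0.98 in the mutant in complete medium (adjusted p = 1.16e-05), while COR27, which answers to cold as well as to the clock, rose in both (1.52, and 3.67 or more). GI also rose by 1.31 on WT starvation, which uses the same WT arrays in complete medium, and by 0.32 on starvation in the mutant. Between the genotypes it differed by -0.01 without Pi and 0.04 after resupply. GI was thus lowest in WT in complete medium, and a different harvest time of that group would also enter the WT starvation changes. The genotype itself may be the cause, and these values do not separate it from the harvest time.

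AT2G17850 and AT5G10040 belong to the low-oxygen genes that were lower in the mutant in complete medium: of 52 genes recalled as induced by low oxygen 25 were measured, and over the 15 of them that the ranking had not named the median was -0.51, with 9 lower, 1 higher (PDC2, 1.22) and 5 not passed (p = 8.18e-07, and p = 0.0177 with an estimated correlation). This is consistent with a low-oxygen state of the WT seedlings in complete medium, the highest of the 6 groups for 8 of the 15, and part of the WT starvation falls of AT4G39675, AT1G33055 and AT5G10040, which use the same arrays, may come from it. The 15 were also lower on WT starvation (9 down and 3 up, median -0.86) and on resupply in WT and mutant (8 and 10 down, 2 and 4 up, medians -0.63 and -0.70), with p = 0.239, 0.185 and 0.144 with an estimated correlation, and the resupply falls do not use those arrays. A labelling batch marked by the low spike-in arrays is argued against, with a median of -0.49 without them. Whether such a state came with the genotype or with how those plates were grown could not be told, since growth conditions per plate were not analysed here.

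PsbI and psbK were higher in the mutant without Pi, by 2.17 and 2.09. A labelling batch marked by the low spike-in arrays is argued against, since with them as a block the changes were 2.31 and 2.24 (adjusted p = 0.00197 and 0.0046). A rise of signal over all chloroplast-encoded photosystem and electron transport genes is also argued against, since the list median was -0.032 with quartiles of -0.171 and 0.253. The 2 genes may share a transcript, which 3 prime arrays do not test.

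AT2G04460, AT5G20790 and AT5G17340 fell less in the mutant than in WT on resupply, while the median over the 1641 starvation-induced probe sets was -0.83 in the mutant and -0.68 in WT, and no cause was tested. CML38, AT1G19210 and EXLA3 fell in the mutant on resupply and less in WT, and no cause was tested.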

How the results depend on the processing

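The spike-in alternatives and the pairs of like responses were chosen only after the data were seen. Named genes were refitted in 4 ways (trend and robust, centred arrays, spike-in block, replicate block): of 325 gene-by-comparison results over 121 genes, 10 lost their call in at least 1, and none reversed there. Of 102 gene list calls, 24 held with an estimated correlation, 100 with a replicate block, 98 with centred arrays, 74 of 101 without the dimmer probe sets, 96 with the spike-in block and 90 without the low spike-in arrays, and none turned. Replicate numbers carried little pairing: 12 of 45 same-number pairs had residual correlations over 0.1 (median -0.007). As a replicate block they gave 125 probe sets for the mutant against WT without Pi. Leaving out the dimmer probe sets gave 7337 for WT starvation, from fewer probe sets tested. A 2-fold minimum, which is stricter, gave 3435 for WT starvation, 1917 for WT resupply, 2659 and 2428 for the same in the mutant, 733, 28 and 748 for the genotypes in complete medium, without Pi and after resupply, and 890 and 868 for the interactions with starvation and resupply. The overlaps under it were 493, 231 and 197 for the planned pairs and 1977 and 1213 for starvation and resupply across genotypes. At an adjusted p of 0.01 the genotype counts were 2314, 57 and 2922 and the interactions 1250 and 1164. Fits to only the groups compared gave 1525 in complete medium, 8094 after resupply, and 1580 and 4017 for the interactions. Array weights gave 667 without Pi, 9266 after resupply and 5843 for the resupply interaction. The cause of these was not tested. Leaving out each array gave 2370 to 4988 in complete medium, 49 to 155 without Pi, 3311 to 5339 after resupply, 1687 to 3555 for the starvation interaction and 1692 to 2886 for the resupply interaction.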

Other observations

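Further gene groups moved with starvation in WT. Expansin and XTH genes of the cell wall rose in 15 of 27 cases and fell in 7, with EXLA3 at 3.68 and EXPA8 at -2.57 (adjusted p = 0.0033, and adjusted p = 0.244 with an estimated correlation). Glutathione transferase genes rose in 6 of 14 cases and fell in 2, with GSTU25 at 2.87 and GSTU18 at -1.2 (adjusted p = 0.00856, and adjusted p = 0.15 with an estimated correlation, and 0.0858 without the dimmer probe sets). Chlorophyll and haem genes fell in 6 of 9 cases and rose in 2, with CHLI2 at -1.66 and HEMA2 at 1.95 (adjusted p = 0.0347, and adjusted p = 0.244 with an estimated correlation, and 0.0729 without the dimmer probe sets). Citrate cycle genes rose in 7 of 14 cases and fell in 1, with SDH1-2 at 0.95 (adjusted p = 0.0293, and adjusted p = 0.15 with an estimated correlation, and 0.154 without the dimmer probe sets). Lists that did not pass held single genes that did: SWEET13 (3.19) and SWEET2 (-1.56) among 14 sugar transporters, TBL26 (2.51) and TBL36 (-1.65) among 22 wall acetylation genes, and AT1G47400 (-2.22) among 13 iron homeostasis genes (adjusted p = 0.393, 0.289 and 0.482). The iron deficiency list had BHLH101 down and AT3G13610 up among 3 (adjusted p = 0.902). NDH genes of the chloroplast fell in 3 of 10 cases, with ndhF at -2.71, a lower bound from a dim signal (adjusted p = 0.2), and 1 of 4 reference genes fell, AT2G32170 at -0.39 (adjusted p = 0.948).

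On resupply in WT, autophagy genes fell in 7 of 10 cases and rose in 1, with ATG8F at -1.84 and ATG8B at 1.03 (adjusted p = 0.0111, and adjusted p = 0.498 with an estimated correlation). Unfolded protein response genes fell in 7 of 12 cases, with the factor genes BZIP28 at -1.07 and BZIP60 at -0.94 (adjusted p = 0.0288, and adjusted p = 0.0777 with an estimated correlation). Auxin response genes fell in 6 of 15 cases, with WES1 at -1.48 and GH3.3 at -1.41 (adjusted p = 0.0303, and adjusted p = 0.191 with an estimated correlation).

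The splits of arrays in this part were planned before. With 3 arrays per group there are 10 splits, too few for a share under 0.05. In each of the 7 comparisons of 2 groups the real split was the 1 of 10 with the most calls. The highest other split gave 822 for the mutant against WT in complete medium and 1 for starvation in the mutant.

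The 3 arrays with low spike-in signal had residual correlations of 0.507 to 0.598 with one another, so they may share a labelling run, and the counts with them as a block were 5547 in complete medium and 240 without Pi. Resupply needed a change of medium, and no group moved from complete to complete medium was analysed here, so effects of the transfer were not separated from those of Pi. Of the touch genes, CML38 fell by 0.64 in WT and 4.49 in the mutant on resupply, after rising by 2.98 and 4.32 on starvation. STZ (-0.09) and WRKY53 (0.02) did not pass in WT, and all 3 fell in the mutant. CML38 is also among the genes recalled as induced by low oxygen. These values from 4 h do not tell whether the transfer had an effect.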
